A study of Pimephales promelas with 38 samples.

How the data were processed

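The study measured transcripts in liver and testis of male fathead minnows (Pimephales promelas) after exposure for 48 h to site or control water, following 48 h of acclimation. Per the labels' protocols, total RNA was extracted, DNase-treated, amplified, labelled with Cy3 and hybridized in a one-colour design, and per the series' design text each replicate was a different fish. A further reference site, C, was not analysed here. The design text also states that 2 arrays failed quality control.

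The scanner files hold spot intensity from Agilent Feature Extraction 9.5.1.1, per the file headers, already background-subtracted in the processed signal. Deposited by the authors beside them is a table of log2 values, normalized per tissue by steps not given in the sources used here. Set against the processed signal of probes well above background, its columns had slopes of 0.833 (liver site A replicate 3) to 1.07. Column medians lay between 5.02 and 5.23 in liver and between 8.05 and 8.17 in testis. The steps behind that table's scale and centring stay unknown. Its direction follows the signal, with rank correlations such as 0.998 for liver UF control replicate 1. All 15208 non-control probes of the 15744 spots carry the description Unknown, and 0 of their identifiers matched the RefSeq gene table of assembly fPimPro1.hap1.1, so 47 gene lists written beforehand were not tested and genes were not averaged.

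From the files, log2 of the processed signal was taken and the 75th percentile of each array's probes subtracted. Spots marked as non-uniform or population outliers were set to missing. A probe was kept in a tissue when well above background on at least 3 arrays of 1 water, which left 10617 in liver and 13394 in testis. All waters of a tissue entered one fit in limma 3.58.1 (R 4.3.3), with moderated variances without trend or robust options and Benjamini-Hochberg adjustment over all probes of a comparison at 0.05. Intervals are 95% intervals from the same fits. Tissue differences were tested in one fit of all 38 arrays over 10383 probes kept in both tissues. Figures were drawn with matplotlib 3.10.9.

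Groups, tests, the alternatives called planned and the rule for named genes were chosen before the data were examined. That rule asked for named genes and, where too few passed, took those of smallest p without a split by direction. As none has a name, it could not be applied as written. It was applied to probes in a changed form, with at most 2 per direction, so the selection used is not the one fixed beforehand. For each comparison with UF control, the 2 higher and 2 lower probes of smallest p were taken, and for each with site D the 3 of smallest p among these. They had to be well above background on at least 2 arrays of each water and not saturated on every array of a water. Where only 2 arrays of a water reached this, the size of the difference is uncertain. That held for UF_Ppr_AF_109459, UF_Ppr_AM_119517, UF_Ppr_AF_100011, UF_Ppr_AF_105079, UF_Ppr_AM_120570, UF_Ppr_AF_101888, UF_Ppr_AF_107581, UF_Ppr_AF_116893 and, against UF control, UF_Ppr_AF_111255. This gave 50 differences in 43 probes. In 46 the arrays of the 2 waters did not overlap, which fixes the sign within each slide, so differences within slides are no independent evidence for probes chosen on the same arrays. Chance gives 2.86% of such separations for 4 arrays against 4 and 5.71% for 3 against 4, before choosing by p.

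The array whose title and source name disagree was placed with site D because the design text gives site A testes only 3 replicates and does not list site D among the groups short of an array. It was also left out and placed in site A as alternatives. Other alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization alone, median scaling, the authors' values, no filter, a stricter filter, outlier spots kept, only the 2 groups in the fit, array weights, trend and robust moderation, the replicate number or the slide as a block, and leaving out each array. Arrays of a tissue were scanned on 1 day, over 3 slides per tissue. A difference between the tissues can therefore not be told apart from scan day or from the slides each tissue was on. Within a tissue, the slide could be fitted as a block.

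The fits were tested on simulated data with 200 probes shifted, each probe keeping its own variance and with 5 draws per comparison. The simulated values were normal and independent between probes, without slide effects or outlying arrays. Recovery in the real arrays, or with another number of changed probes, may therefore differ. For liver site A against UF control (10617 probes), 14.3% of probes shifted by a log2 of 1 were recovered, 59.1% at 2 and 82.4% at 3. For testis site A against UF control (13394 probes) the shares were 16.1%, 56.4% and 79.1%. For the tissue difference in the response to site A water (10383 probes) they were 5.67%, 39.4% and 66.4%. The number of arrays limits the precision: the median 95% half-width was 0.89 for liver site A against UF control and 0.80 for testis site B against UF control.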

Results

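Transcript levels were measured in liver and testis of reproductively mature male fathead minnows kept for 48 h in water from 3 sites on Eglin Air Force Base (A, B and E), in water from reference site D, or in UF control water, which was carbon-filtered and dechlorinated tap water. The water was renewed every 12 h. Each one-colour array carried the RNA of 1 fish and tissue. There were 19 liver arrays, with 4 fish per water except 3 for site E, and 19 testis arrays, with 4 fish per water except 3 for site A. One testis array has a title naming site A and a sample source naming site D; it was placed with site D. The site D values in testis include it, and no direction of a named probe turned when it was left out or placed in site A. This holds for direction only, and the sizes of site A and site D differences in testis can depend on its placement. Values are log2 signals relative to the 75th percentile of the same array, and a difference of 1 is 2-fold. The array's 15208 probes carry no gene names. Of them 11862 have contig names and 3309 have names that start with gi_, which are sequence identifiers and not contigs. Probes are given by identifier, by this name, printed after the word contig for both kinds, and by sequence.

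Signal over background set 1 liver slide apart. Liver slide 2, with 7 arrays, had a median array brightness 12.3-fold below that of the other liver slides. Its arrays had 7647 to 8856 probes well above background, against 10195 to 11733 on the other liver slides. Testis arrays had 10926 to 14061. Liver slide 2 carried 1 array of UF control, 1 of site A, 2 of site B, 2 of site D and 1 of site E. On average 10211 ± 1826 probes (SD, n = 4) were well above background in UF control livers and 10466 ± 1546 (SD, n = 4) in site A livers. No pair of arrays of a tissue correlated above 0.971 over all probes, so none was a duplicate. Liver site A replicate 3, testis site B replicate 3 and testis site E replicate 3 are called the 3 arrays that stand apart, and leaving them out was chosen after seeing the data.

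**Figure D1:**
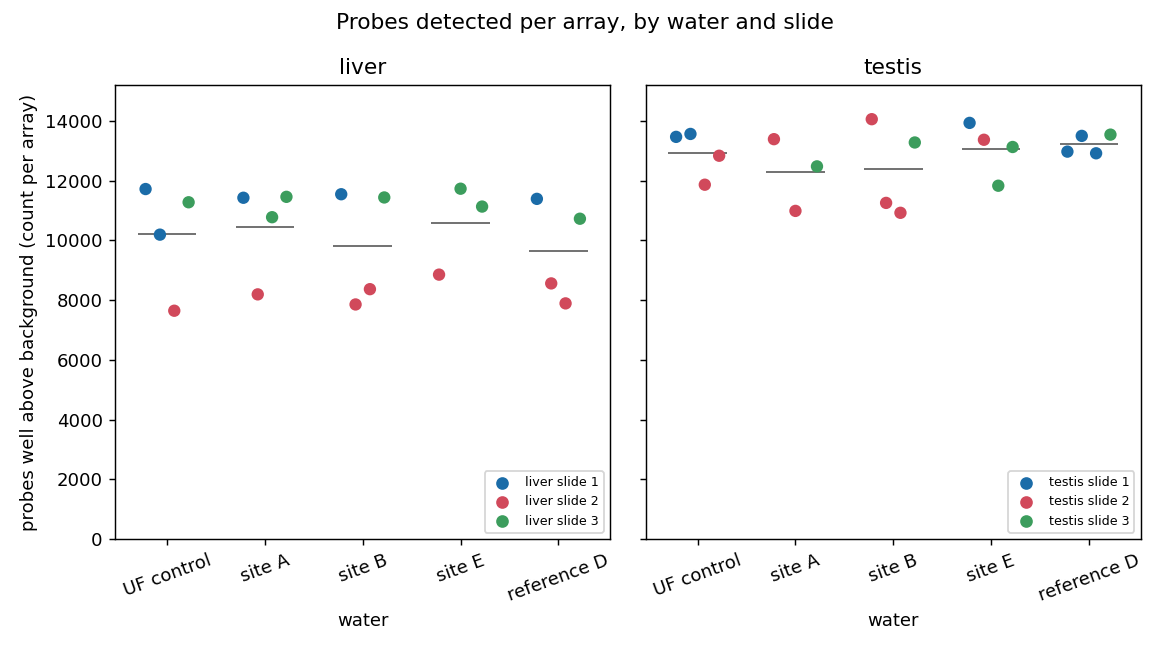
Number of probes well above background (y axis) on each array, by water (x axis), for liver and testis; points are arrays coloured by slide and the grey line is the mean of a water. The 7 arrays of liver slide 2 lie between 7647 and 8856 in every water, below all other liver arrays.

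The first comparison asked whether site A water altered liver transcripts relative to clean laboratory water. Probes on both sides separated the arrays of the 2 waters without passing the test. Site A replicate 3 had 1143 non-uniform spots, where the other site A livers had 0 to 5. It differed beyond the spots set to missing. Its mean negative control signal was 38.8, with 5.58 the highest among the other livers, and 141 of its spots were saturated. On it 271 probes lay at least 8-fold below the liver median, against 10 to 40 on each other liver array. UF_Ppr_AF_112711 (contig FJU.9835.C1___1_nrnt, probe sequence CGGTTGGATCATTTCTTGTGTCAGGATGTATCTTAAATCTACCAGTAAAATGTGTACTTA) averaged -0.67 ± 0.55 (SD, n = 4) after site A water and -2.11 ± 0.60 (SD, n = 4) after UF control water. The difference, 1.44 (SE 0.32, 95% interval 0.76 to 2.11), was 2.71-fold higher with site A. UF_Ppr_AF_113142 (contig FJU.1718.C1___1_nrnt) differed by 2.69 (SE 0.62), with 4.59 ± 1.57 (n = 4) against 1.90 ± 0.84 (n = 4). UF_Ppr_AF_102046 (contig FJU_SB_30.166.C1___1_nrnt, probe sequence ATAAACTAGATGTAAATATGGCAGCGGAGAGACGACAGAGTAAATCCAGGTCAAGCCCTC) averaged -3.12 ± 0.60 (SD, n = 4) after site A water and -1.48 ± 0.38 (SD, n = 4) after UF control water. Its difference, -1.64 (SE 0.35, 95% interval -2.38 to -0.89), was 3.11-fold lower with site A. UF_Ppr_AF_103240 (contig gi_73464273___1_nr0nt1) differed by -2.08 (SE 0.47), with -5.73 ± 0.65 (n = 4) against -3.65 ± 0.69 (n = 4). After site A water, 0 of 10617 liver probes passed in limma, and the named probes had an adjusted p of 0.681. 737 liver probes had an unadjusted p under 0.05, against 531 expected by chance, a count that ran from 325 with only the 2 groups in the fit to 804 with median scaling. Within slides, UF_Ppr_AF_102046 differed by -1.01 on slide 1, -1.70 on slide 2 and -1.85 on slide 3, and limma with the slide as a block called 0. Without site A replicate 2, 1 probe passed, UF_Ppr_AF_117050, chosen after its values were seen. That unadjusted count was 401 without UF control replicate 1, 497 without site A replicate 3 and 1148 without site A replicate 1.

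In livers of fish held in site B water, the probes of smallest p differed by between 2.11-fold and 7.12-fold. UF_Ppr_AF_113282 (contig FJU.11680.C1___1_nrnt, probe sequence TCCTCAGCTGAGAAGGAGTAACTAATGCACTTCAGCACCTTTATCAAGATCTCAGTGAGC) averaged -0.44 ± 1.25 (SD, n = 4) after site B water and -3.28 ± 0.35 (SD, n = 4) after UF control water. This gap, 2.83 (SE 0.59, 95% interval 1.58 to 4.08), was 7.12-fold higher with site B. UF_Ppr_AF_106507 (contig gi_73505786___1_nr0nt1) differed by 2.38 (SE 0.53), with -1.72 ± 0.47 (n = 4) against -4.10 ± 0.50 (n = 4). UF_Ppr_AF_110129 (contig FJU.1330.C2___1rc_nrnt, probe sequence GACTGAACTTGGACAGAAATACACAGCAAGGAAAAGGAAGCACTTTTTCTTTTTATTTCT) averaged 0.97 ± 0.33 (SD, n = 4) after site B water and 3.34 ± 0.50 (SD, n = 4) after UF control water. That contrast, -2.37 (SE 0.49, 95% interval -3.41 to -1.34), was 5.19-fold lower with site B. UF_Ppr_AF_108217 (contig FJU.10748.C1___1rc_nrnt) differed by -1.07 (SE 0.24), with 2.57 ± 0.29 (n = 4) against 3.64 ± 0.36 (n = 4). After site B water, 0 of 10617 liver probes passed in limma, and the named probes had an adjusted p of 0.661. 540 liver probes had an unadjusted p under 0.05, against 531 expected by chance, a count that ran from 388 with only the 6767 probes above background on every array to 942 with array weights. Within slides, UF_Ppr_AF_110129 differed by -2.12 on slide 1, -1.70 on slide 2 and -3.11 on slide 3, and limma with the slide as a block called 0.

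Site E livers numbered 3, and UF_Ppr_AF_113058 was 18.2-fold higher in them than in UF control livers. UF_Ppr_AF_113058 (contig FJU.34.C5___1rc_nrnt, probe sequence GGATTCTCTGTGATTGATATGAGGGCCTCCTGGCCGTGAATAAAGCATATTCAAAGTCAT) averaged 0.30 ± 1.18 (SD, n = 3) after site E water and -3.89 ± 0.84 (SD, n = 4) after UF control water. The contrast, 4.19 (SE 0.83, 95% interval 2.44 to 5.94), was 18.2-fold higher with site E. UF_Ppr_AF_100646 (contig FJU.6310.C4___1_nrnt) differed by 1.08 (SE 0.25), with 1.67 ± 0.05 (n = 3) against 0.58 ± 0.34 (n = 4). UF_Ppr_AF_101754 (contig FJU.7036.C2___1_nrnt, probe sequence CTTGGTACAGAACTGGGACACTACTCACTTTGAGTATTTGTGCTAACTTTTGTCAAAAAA) averaged 0.48 ± 0.16 (SD, n = 3) after site E water and 1.39 ± 0.20 (SD, n = 4) after UF control water. Its gap, -0.91 (SE 0.21, 95% interval -1.35 to -0.47), was 1.88-fold lower with site E. UF_Ppr_AF_109459 (contig FJU.10814.C2___1rc_nrnt) differed by -2.50 (SE 0.67), with -4.15 ± 0.25 (n = 3) against -1.66 ± 1.1 (n = 4). After site E water, 0 of 10617 liver probes passed in limma, and the named probes had an adjusted p of 0.999919. 389 liver probes had an unadjusted p under 0.05, against 531 expected by chance, a count that ran from 233 with only the 6767 probes above background on every array to 697 with array weights. Within slides, UF_Ppr_AF_113058 differed by 1.99 on slide 2 and 5.86 on slide 3, and limma with the slide as a block called 0. That unadjusted count was 257 without site E replicate 2.

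Reference site D served as the field reference, and its livers were set against UF control to show what reference field water did. Both higher probes came from one contig, FJU.4333.C1. UF_Ppr_AF_110129 was lower in these livers as in site B livers, both against the same 4 control arrays. UF_Ppr_AF_104563 (contig FJU.4333.C1___1_nr0nt1, probe sequence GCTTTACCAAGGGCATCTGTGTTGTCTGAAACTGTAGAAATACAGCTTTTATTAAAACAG) averaged 4.58 ± 0.62 (SD, n = 4) after reference site D water and 2.63 ± 0.44 (SD, n = 4) after UF control water. This difference, 1.94 (SE 0.41, 95% interval 1.07 to 2.81), was 3.84-fold higher with reference site D. UF_Ppr_AM_119517 (contig FJU.4333.C1___1_nr0nt1_ms) differed by 2.37 (SE 0.56), with -3.45 ± 0.69 (n = 4) against -5.82 ± 0.93 (n = 4). It was well above background on only 2 of the 4 UF control livers, which leaves the size of its difference uncertain. UF_Ppr_AF_110129 (contig FJU.1330.C2___1rc_nrnt, probe sequence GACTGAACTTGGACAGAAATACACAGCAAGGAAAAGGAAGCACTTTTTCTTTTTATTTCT) averaged 0.85 ± 0.64 (SD, n = 4) after reference site D water and 3.34 ± 0.50 (SD, n = 4) after UF control water. The difference, -2.49 (SE 0.49, 95% interval -3.52 to -1.46), was 5.62-fold lower with reference site D. UF_Ppr_AF_118730 (contig FJU.7831.C2___1_nrnt) differed by -1.28 (SE 0.27), with -2.22 ± 0.26 (n = 4) against -0.94 ± 0.18 (n = 4). After reference site D water, 0 of 10617 liver probes passed in limma, and the named probes had adjusted p from 0.439 to 0.819. 440 liver probes had an unadjusted p under 0.05, against 531 expected by chance, a count that ran from 280 with only the 6767 probes above background on every array to 706 with the slide as a block and the 3 arrays that stand apart left out. Within slides, UF_Ppr_AF_110129 differed by -3.16 on slide 1, -1.67 on slide 2 and -2.58 on slide 3, and limma with the slide as a block called 0.

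**Figure D2:**
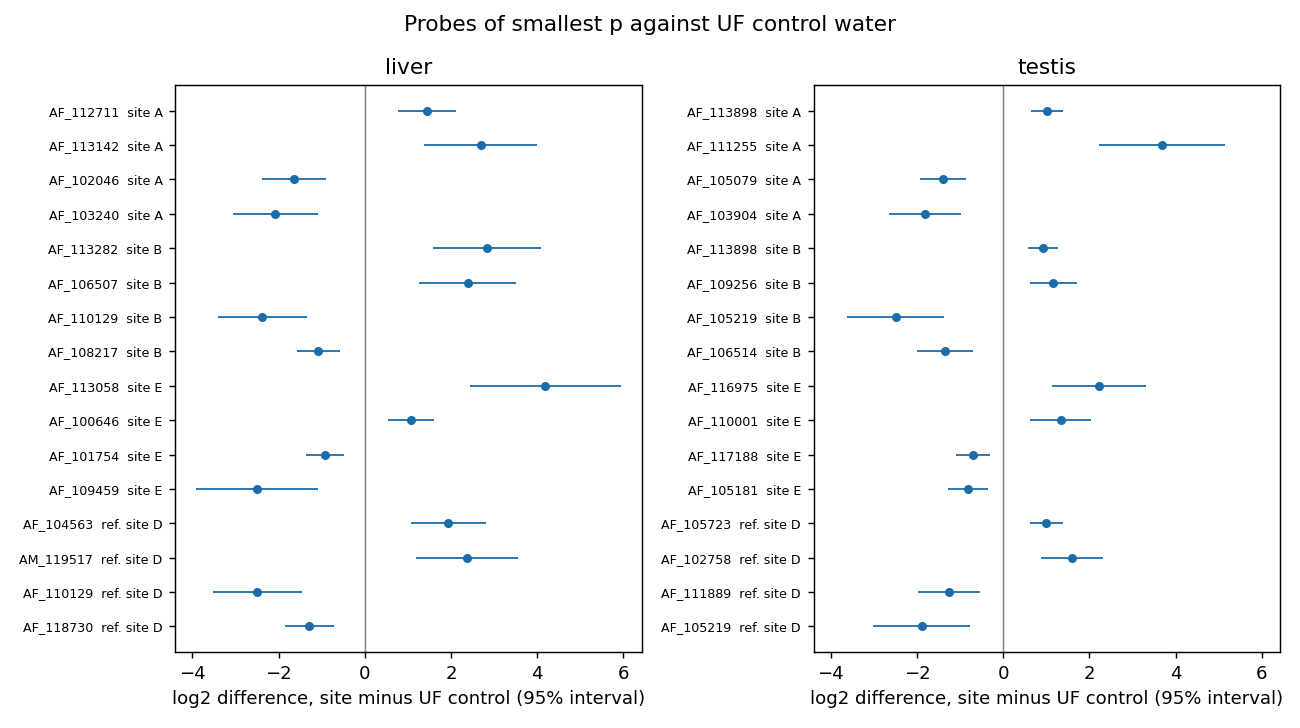
Log2 difference, site minus UF control (x axis), of the probes of smallest p in each comparison with UF control water, for liver and testis; points are limma estimates and bars their 95% intervals. The liver differences run from -2.50 to 4.19, and no probe passed after adjustment for all probes tested.

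Against reference site D, the question was whether site A water differed from other field water. UF_Ppr_AF_115273 was 14.7-fold lower in site A livers. The site A livers included replicate 3, with its 1143 non-uniform spots. UF_Ppr_AF_108876 (contig FJU.12883.C1___1_nrnt, probe sequence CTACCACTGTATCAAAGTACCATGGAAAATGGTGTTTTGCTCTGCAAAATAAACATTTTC) averaged -0.71 ± 0.60 (SD, n = 4) after site A water and -2.78 ± 0.46 (SD, n = 4) after site D water. Its difference, 2.07 (SE 0.39, 95% interval 1.24 to 2.90), was 4.20-fold higher with site A. UF_Ppr_AF_101561 (contig FJU.3769.C1___1rc_nrnt) differed by 1.66 (SE 0.33), with 2.64 ± 0.47 (n = 4) against 0.98 ± 0.51 (n = 4). UF_Ppr_AF_115273 (contig gi_73448744___1_nr1nt0, probe sequence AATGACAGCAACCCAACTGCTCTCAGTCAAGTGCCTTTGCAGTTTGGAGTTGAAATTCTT) averaged -4.56 ± 0.41 (SD, n = 4) after site A water and -0.68 ± 0.87 (SD, n = 4) after site D water. This gap, -3.88 (SE 0.84, 95% interval -5.65 to -2.11), was 14.7-fold lower with site A. After site A water, 0 of 10617 liver probes passed in limma, and the named probes had an adjusted p of 0.436. 909 liver probes had an unadjusted p under 0.05, against 531 expected by chance, a count that ran from 499 with only the 2 groups in the fit to 997 with the authors' values. Within slides, UF_Ppr_AF_108876 differed by 2.18 on slide 1, 1.1 on slide 2 and 2.90 on slide 3, and limma with the slide as a block called 1. The slide block called UF_Ppr_AF_104571, and 1 probe passed without site A replicate 2 (UF_Ppr_AF_117050) or without site A replicate 3 (UF_Ppr_AF_107647), all chosen after their values were seen. In site D livers UF_Ppr_AF_104571 was well above background only on replicate 4, so the size of its difference is uncertain. Without site A replicate 3 the unadjusted count was 764.

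Site B and reference site D livers had the same number of arrays on each slide. UF_Ppr_AF_115323 (contig gi_72763070___1rc_nr0nt1, probe sequence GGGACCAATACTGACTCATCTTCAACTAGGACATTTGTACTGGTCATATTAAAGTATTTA) averaged -2.82 ± 0.33 (SD, n = 4) after site B water and -3.85 ± 0.27 (SD, n = 4) after site D water. That contrast, 1.03 (SE 0.24, 95% interval 0.52 to 1.55), was 2.04-fold higher with site B. UF_Ppr_AF_112288 (contig FJU.13882.C1___1_nrnt, probe sequence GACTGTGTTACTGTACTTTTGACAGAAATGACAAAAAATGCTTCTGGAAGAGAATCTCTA) averaged -0.04 ± 0.53 (SD, n = 4) after site B water and 1.73 ± 0.52 (SD, n = 4) after site D water. The contrast, -1.77 (SE 0.39, 95% interval -2.59 to -0.95), was 3.41-fold lower with site B. UF_Ppr_AF_100011 (contig gi_72475562___1rc_nrnt) differed by -1.16 (SE 0.26), with -4.96 ± 0.26 (n = 4) against -3.80 ± 0.50 (n = 4). After site B water, 0 of 10617 liver probes passed in limma, and the named probes had an adjusted p of 0.961. 518 liver probes had an unadjusted p under 0.05, against 531 expected by chance, a count that ran from 306 with only the 6767 probes above background on every array to 955 with the slide as a block and the 3 arrays that stand apart left out. Within slides, UF_Ppr_AF_112288 differed by -1.77 on slide 1, -1.89 on slide 2 and -1.53 on slide 3, and limma with the slide as a block called 0. That unadjusted count was 305 without site D replicate 2.

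UF_Ppr_AF_113058 was higher in site E livers than in site D livers, as against UF control, both with the same 3 site E arrays, and arrays of the 2 waters overlapped for it. UF_Ppr_AF_118730 (contig FJU.7831.C2___1_nrnt, probe sequence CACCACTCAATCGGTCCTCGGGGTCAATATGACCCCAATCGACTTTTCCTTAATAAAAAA) averaged -0.97 ± 0.46 (SD, n = 3) after site E water and -2.22 ± 0.26 (SD, n = 4) after site D water. Its gap, 1.25 (SE 0.29, 95% interval 0.65 to 1.86), was 2.38-fold higher with site E. UF_Ppr_AF_113058 (contig FJU.34.C5___1rc_nrnt) differed by 3.47 (SE 0.83), with 0.30 ± 1.18 (n = 3) against -3.17 ± 1.83 (n = 4). UF_Ppr_AF_109053 (contig gi_72712469___1rc_nr0nt1, probe sequence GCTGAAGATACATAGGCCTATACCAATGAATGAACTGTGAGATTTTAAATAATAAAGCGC) averaged -5.39 ± 0.75 (SD, n = 3) after site E water and -2.57 ± 0.90 (SD, n = 4) after site D water. This difference, -2.82 (SE 0.76, 95% interval -4.43 to -1.20), was 7.05-fold lower with site E. After site E water, 0 of 10617 liver probes passed in limma, and the named probes had an adjusted p of 0.999895. 309 liver probes had an unadjusted p under 0.05, against 531 expected by chance, a count that ran from 214 with only the 6767 probes above background on every array to 581 with array weights. Within slides, UF_Ppr_AF_118730 differed by 1.82 on slide 2 and 0.93 on slide 3, and limma with the slide as a block called 0.

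In testis, site A water gave the smallest adjusted p of the comparisons with UF control water in either tissue. UF_Ppr_AF_113898 (contig FJU.3011.C1___1_nrnt, probe sequence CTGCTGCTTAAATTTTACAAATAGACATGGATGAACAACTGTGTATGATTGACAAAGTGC) averaged 0.40 ± 0.09 (SD, n = 3) after site A water and -0.61 ± 0.18 (SD, n = 4) after UF control water. The difference, 1.01 (SE 0.18, 95% interval 0.64 to 1.38), was 2.02-fold higher with site A. UF_Ppr_AF_111255 (contig gi_73497537___1_nrnt) differed by 3.69 (SE 0.69), with -2.97 ± 1.38 (n = 3) against -6.66 ± 0.48 (n = 4). It was well above background on only 2 of the 4 UF control testes, which leaves the size of its difference uncertain. On the array with conflicting labels, placed in site D, it read -7.11, inside the UF control range of -7.31 to -6.14. With that array in site A, the arrays of the 2 waters would overlap for this probe. UF_Ppr_AF_105079 (contig FJU.6723.C1___1_nr0nt1, probe sequence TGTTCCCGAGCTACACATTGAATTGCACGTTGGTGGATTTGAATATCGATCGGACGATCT) averaged -6.15 ± 0.21 (SD, n = 3) after site A water and -4.76 ± 0.21 (SD, n = 4) after UF control water. Its difference, -1.39 (SE 0.25, 95% interval -1.93 to -0.86), was 2.62-fold lower with site A. UF_Ppr_AF_103904 (contig FJU.808.C1___1_nrnt) differed by -1.82 (SE 0.39), with 2.61 ± 0.24 (n = 3) against 4.43 ± 0.55 (n = 4). After site A water, 0 of 13394 testis probes passed in limma, and the named probes had adjusted p from 0.261 to 0.570. 551 probes lay at an unadjusted p under 0.05, where chance gives 670, a count that ran from 376 with only the 9625 probes above background on every array to 1013 with array weights. Within slides, UF_Ppr_AF_113898 differed by 0.92 on slide 2, the only slide holding both waters, and limma with the slide as a block called 0. With array weights limma called 3 probes, all among those named, and with only these 2 groups in the fit it called 1, UF_Ppr_AF_117050, chosen after its values were seen. That unadjusted count was 869 without UF control replicate 3.

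UF_Ppr_AF_113898 was also the higher probe of smallest p in site B testes, against the same 4 control arrays. Site B replicate 3 carried a dark patch of 1433 spots at its centre, which held 1 spot of UF_Ppr_AF_106514. UF_Ppr_AF_113898 (contig FJU.3011.C1___1_nrnt, probe sequence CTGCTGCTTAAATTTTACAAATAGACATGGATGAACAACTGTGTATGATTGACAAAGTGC) averaged 0.32 ± 0.15 (SD, n = 4) after site B water and -0.61 ± 0.18 (SD, n = 4) after UF control water. This gap, 0.93 (SE 0.16, 95% interval 0.59 to 1.28), was 1.91-fold higher with site B. UF_Ppr_AF_109256 (contig gi_72427269___1rc_nrnt) differed by 1.17 (SE 0.26), with -4.19 ± 0.34 (n = 4) against -5.36 ± 0.31 (n = 4). UF_Ppr_AF_105219 (contig FJU.2008.C1___1_nrnt, probe sequence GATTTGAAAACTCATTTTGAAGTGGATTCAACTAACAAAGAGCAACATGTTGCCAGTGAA) averaged -4.21 ± 0.57 (SD, n = 4) after site B water and -1.72 ± 0.87 (SD, n = 4) after UF control water. That contrast, -2.49 (SE 0.53, 95% interval -3.62 to -1.37), was 5.63-fold lower with site B. UF_Ppr_AF_106514 (contig FJU.10032.C2___1rc_nrnt-1) differed by -1.35 (SE 0.31), with -5.28 ± 0.08 (n = 4) against -3.93 ± 0.43 (n = 4). After site B water, 0 of 13394 testis probes passed in limma, and the named probes had adjusted p from 0.474 to 0.988. 474 probes lay at an unadjusted p under 0.05, where chance gives 670, a count that ran from 352 with only the 9625 probes above background on every array to 944 with the slide as a block and the 3 arrays that stand apart left out. Within slides, UF_Ppr_AF_113898 differed by 0.76 on slide 2, the only slide holding both waters, and limma with the slide as a block called 0. Without UF control replicate 4, 1 probe passed, UF_Ppr_AF_112593, chosen after its values were seen.

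At an unadjusted p under 0.05, 640 probes were higher in site E testes and 144 lower, but 339 and 322 under median scaling. Replicate 3 of this group carried a dark patch of 1759 spots and, over 262 probes typical of liver, a median of -0.58 where UF control testes had -4.92 to -3.48. UF_Ppr_AF_116975 (contig FJU_SB_30.161.C4___1_nrnt, probe sequence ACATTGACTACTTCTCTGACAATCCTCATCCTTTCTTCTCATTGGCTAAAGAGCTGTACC) averaged -5.42 ± 1.33 (SD, n = 4) after site E water and -7.64 ± 0.77 (SD, n = 4) after UF control water. The contrast, 2.23 (SE 0.51, 95% interval 1.14 to 3.31), was 4.69-fold higher with site E. UF_Ppr_AF_110001 (contig FJU.12125.C1___1_nrnt) differed by 1.34 (SE 0.33), with -4.30 ± 0.57 (n = 4) against -5.64 ± 0.41 (n = 4). For both of these higher probes, arrays of the 2 waters overlapped. UF_Ppr_AF_117188 (contig FJU.12657.C1___1_nrnt, probe sequence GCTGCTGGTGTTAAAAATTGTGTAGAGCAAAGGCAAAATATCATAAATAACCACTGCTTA) averaged -0.99 ± 0.18 (SD, n = 4) after site E water and -0.29 ± 0.14 (SD, n = 4) after UF control water. Its gap, -0.70 (SE 0.19, 95% interval -1.1 to -0.31), was 1.63-fold lower with site E. UF_Ppr_AF_105181 (contig FJU.190.C5___1_nr0nt1) differed by -0.82 (SE 0.22), with 3.09 ± 0.15 (n = 4) against 3.91 ± 0.27 (n = 4). After site E water, 0 of 13394 testis probes passed in limma, and the named probes had an adjusted p of 0.802. 784 probes lay at an unadjusted p under 0.05, where chance gives 670, a count that ran from 532 with only the 9625 probes above background on every array to 889 with the dark patch set to missing. Within slides, UF_Ppr_AF_116975 differed by 2.18 on slide 1 and 2.11 on slide 2, and limma with the slide as a block called 0. That unadjusted count was 1459 without site E replicate 1, 499 without UF control replicate 3, 496 without site E replicate 4.

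Testes from reference site D, including the array with conflicting labels, had the fewest probes at an unadjusted p under 0.05 among the testis comparisons. UF_Ppr_AF_105723 (contig FJU.2137.C4___1rc_nrnt, probe sequence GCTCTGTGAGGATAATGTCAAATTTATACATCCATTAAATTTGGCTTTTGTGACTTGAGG) averaged 3.26 ± 0.24 (SD, n = 4) after reference site D water and 2.26 ± 0.26 (SD, n = 4) after UF control water. This difference, 1.0 (SE 0.18, 95% interval 0.62 to 1.38), was 2.0-fold higher with reference site D. UF_Ppr_AF_102758 (contig FJU.9498.C1___1_nrnt) differed by 1.60 (SE 0.34), with -0.71 ± 0.26 (n = 4) against -2.31 ± 0.63 (n = 4). UF_Ppr_AF_111889 (contig FJU_SB_30.603.C1___1_nrnt, probe sequence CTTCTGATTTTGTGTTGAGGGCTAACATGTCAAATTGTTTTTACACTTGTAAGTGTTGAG) averaged -2.62 ± 0.66 (SD, n = 4) after reference site D water and -1.36 ± 0.54 (SD, n = 4) after UF control water. The difference, -1.26 (SE 0.34, 95% interval -1.98 to -0.53), was 2.39-fold lower with reference site D, and arrays of the 2 waters overlapped for this probe. UF_Ppr_AF_105219 (contig FJU.2008.C1___1_nrnt) differed by -1.89 (SE 0.53), with -3.61 ± 0.33 (n = 4) against -1.72 ± 0.87 (n = 4). After reference site D water, 0 of 13394 testis probes passed in limma, and the named probes had adjusted p from 0.582 to 0.999902. 323 probes lay at an unadjusted p under 0.05, where chance gives 670, a count that ran from 222 with only the 9625 probes above background on every array to 566 with array weights. Within slides, UF_Ppr_AF_105723 differed by 1.22 on slide 1, the only slide holding both waters, and limma with the slide as a block called 0. The unadjusted count was 341 without the array with conflicting labels.

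**Figure D3:**
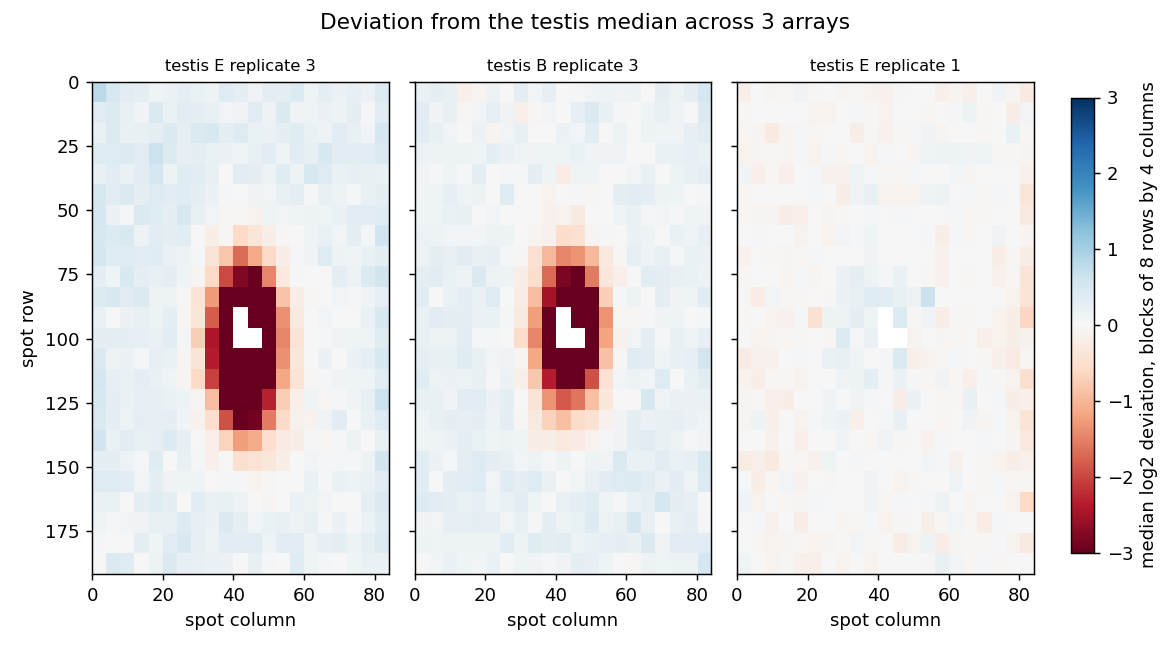
Median log2 deviation from the testis median in blocks of 8 rows by 4 columns of spots (y axis spot row, x axis spot column) on 3 testis arrays; white blocks at the centre hold no probe judged. Site E replicate 3 and site B replicate 3 have a dark central patch, and site E replicate 1 has none.

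Site A testes numbered 3 and site D testes 4, with 1 slide holding both. UF_Ppr_AF_111255 was higher after site A water, as against UF control, both with the same 3 site A arrays. The array with conflicting labels read -7.11 for it, below the other site D testes (-6.47 to -5.18). With that array in site A, the arrays of the 2 waters would overlap here too. UF_Ppr_AF_111255 (contig gi_73497537___1_nrnt, probe sequence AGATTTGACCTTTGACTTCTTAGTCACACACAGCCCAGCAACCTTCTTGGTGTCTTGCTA) averaged -2.97 ± 1.38 (SD, n = 3) after site A water and -6.06 ± 0.89 (SD, n = 4) after site D water. Its difference, 3.08 (SE 0.69, 95% interval 1.63 to 4.54), was 8.48-fold higher with site A. UF_Ppr_AF_113183 (contig FJU.5945.C6___1rc_nrnt-1, probe sequence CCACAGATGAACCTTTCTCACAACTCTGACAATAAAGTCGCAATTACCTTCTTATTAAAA) averaged 1.78 ± 0.22 (SD, n = 3) after site A water and 3.37 ± 0.35 (SD, n = 4) after site D water. This gap, -1.60 (SE 0.33, 95% interval -2.30 to -0.89), was 3.02-fold lower with site A. UF_Ppr_AM_120570 (contig gi_73719597___1_nrnt_ms) differed by -1.56 (SE 0.35), with -6.70 ± 0.58 (n = 3) against -5.14 ± 0.26 (n = 4). After site A water, 0 of 13394 testis probes passed in limma, and the named probes had an adjusted p of 0.909. 600 probes lay at an unadjusted p under 0.05, where chance gives 670, a count that ran from 360 with only the 9625 probes above background on every array to 1036 with the slide as a block and the 3 arrays that stand apart left out. Within slides, UF_Ppr_AF_113183 differed by -2.05 on slide 3, the only slide holding both waters, and limma with the slide as a block called 0. Without site A replicate 3, 1 probe passed, UF_Ppr_AF_117725, chosen after its values were seen.

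Site B and site D testes shared 1 slide, and the site B testes included replicate 3 with its dark patch of 1433 spots. UF_Ppr_AF_111443 (contig FJU.12452.C1___1_nrnt, probe sequence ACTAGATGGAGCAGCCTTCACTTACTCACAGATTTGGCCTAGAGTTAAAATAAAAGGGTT) averaged -1.91 ± 0.04 (SD, n = 4) after site B water and -3.02 ± 0.26 (SD, n = 4) after site D water. That contrast, 1.11 (SE 0.26, 95% interval 0.56 to 1.65), was 2.15-fold higher with site B. UF_Ppr_AF_101888 (contig gi_72737443___1_nrnt, probe sequence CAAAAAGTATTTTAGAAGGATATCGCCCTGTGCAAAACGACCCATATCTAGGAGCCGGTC) averaged -6.77 ± 0.35 (SD, n = 4) after site B water and -5.38 ± 0.31 (SD, n = 4) after site D water. The contrast, -1.39 (SE 0.32, 95% interval -2.06 to -0.72), was 2.62-fold lower with site B. UF_Ppr_AF_107581 (contig FJU.13060.C1___1rc_nrnt) differed by -1.47 (SE 0.34), with -6.23 ± 0.29 (n = 4) against -4.77 ± 0.54 (n = 4). Both lower probes were well above background on only 2 of the 4 site B testes, so the sizes of their differences are uncertain. After site B water, 0 of 13394 testis probes passed in limma, and the named probes had an adjusted p of 0.874. 703 probes lay at an unadjusted p under 0.05, where chance gives 670, a count that ran from 500 with only the 9625 probes above background on every array to 1410 with the slide as a block and the 3 arrays that stand apart left out. Within slides, UF_Ppr_AF_101888 differed by -1.71 on slide 3, the only slide holding both waters, and limma with the slide as a block called 1. The slide block called UF_Ppr_AF_104603, and with only these 2 groups in the fit limma called 3 (UF_Ppr_AF_104603, UF_Ppr_AF_101077 and UF_Ppr_AF_114560), chosen after their values were seen. In site B testes, UF_Ppr_AF_104603 and UF_Ppr_AF_101077 were well above background on no array, and UF_Ppr_AF_114560 only on replicate 1. The sizes of these differences are therefore uncertain.

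The smallest p of any probe in testis belonged to UF_Ppr_AF_105723, lower after site E water than after site D water. The site E testes included replicate 3, with its dark patch of 1759 spots and its liver-typical median of -0.58. UF_Ppr_AF_117077 (contig FJU.7853.C1___1_nrnt, probe sequence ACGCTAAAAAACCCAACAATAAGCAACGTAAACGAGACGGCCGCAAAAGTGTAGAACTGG) averaged -5.27 ± 0.66 (SD, n = 4) after site E water and -6.34 ± 0.13 (SD, n = 4) after site D water. Its gap, 1.07 (SE 0.26, 95% interval 0.51 to 1.63), was 2.1-fold higher with site E. UF_Ppr_AF_116893 (contig FJU.10292.C1___1_nrnt) differed by 1.74 (SE 0.45), with -5.39 ± 1.02 (n = 4) against -7.13 ± 0.48 (n = 4). UF_Ppr_AF_105723 (contig FJU.2137.C4___1rc_nrnt, probe sequence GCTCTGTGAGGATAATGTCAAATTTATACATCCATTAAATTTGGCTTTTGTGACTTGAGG) averaged 2.17 ± 0.08 (SD, n = 4) after site E water and 3.26 ± 0.24 (SD, n = 4) after site D water. This difference, -1.09 (SE 0.18, 95% interval -1.47 to -0.70), was 2.12-fold lower with site E. After site E water, 0 of 13394 testis probes passed in limma, and the named probes had adjusted p from 0.228 to 0.956. 404 probes lay at an unadjusted p under 0.05, where chance gives 670, a count that ran from 302 with only the 9625 probes above background on every array to 508 with array weights. Within slides, UF_Ppr_AF_105723 differed by -1.03 on slide 1 and -1.06 on slide 3, and limma with the slide as a block called 0. Limma with trend and robust moderation called this probe, and without testis site E replicate 3 it called 1 other, UF_Ppr_AM_119974, chosen after its values were seen. UF_Ppr_AM_119974 was well above background on no site D testis, and not on the site E replicate 3 left out (-8.60). The size of its difference is therefore uncertain. That unadjusted count was 252 without site D replicate 1, 810 without site E replicate 1, 685 without site D replicate 4.

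Whether liver and testis responded differently to a water was tested over 10383 probes as the difference of the 2 tissues' differences from UF control. In limma 0 probes passed for site A (smallest adjusted p 0.0771), site B (0.776), site E (0.394) or reference site D (0.763). At an unadjusted p under 0.05 there were 437, 424, 297 and 255 probes, where chance gives 519. With paired fish as a random block there were 717, 667, 492 and 390. These pairs were inferred from the arrays themselves, by the matching described below, and not from labels. A pair joined liver site A replicate 2 with the testis array with conflicting labels, which stayed in site D in this fit. The counts with this block are therefore uncertain. Under quantile normalization, under the authors' values and with paired fish as a random block, limma called 1 probe for site A, UF_Ppr_AF_105208, chosen after its values were seen.

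Correlations of the responses to different waters, taken across probes, lay within the simulated 95% range for every pair of waters in both tissues; probes are not independent replicates. In liver, site E and reference site D responses had a Pearson correlation of 0.538 (covariance 0.207), where 100 simulations without effects against shared controls gave a median of 0.475 (95% range 0.0884 to 0.741, covariance 0.175). With the 4 control arrays split 2 and 2 in 6 ways, it averaged 0.0889. Site A and site B livers gave 0.371 against a simulated 0.531, and -0.0230 with split controls. In testis the site A and site B responses gave 0.492 against a simulated 0.512, and 0.00566 with split controls. Site A and site E gave 0.286, below the simulated 0.472, and -0.0826 with split controls.

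Liver and testis arrays could be matched through probes that are on in some fish and off in others. Over 58 such probes, 18 liver arrays and 18 testis arrays were each other's best match by Spearman correlation, and 17 of these pairs had the same water in both tissues under the placement used. A permutation test over 100000 shuffles of the waters never gave more than 12 pairs (one-sided permutation p = 1e-05, the smallest it can give). Shuffling waters tests whether matched arrays share a water, which probes responding to a water in both tissues could also give. It cannot tell whether they come from the same fish. The array with conflicting labels matched a site A liver (0.79), with 0.19 for its best site D liver.

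**Figure D4:**
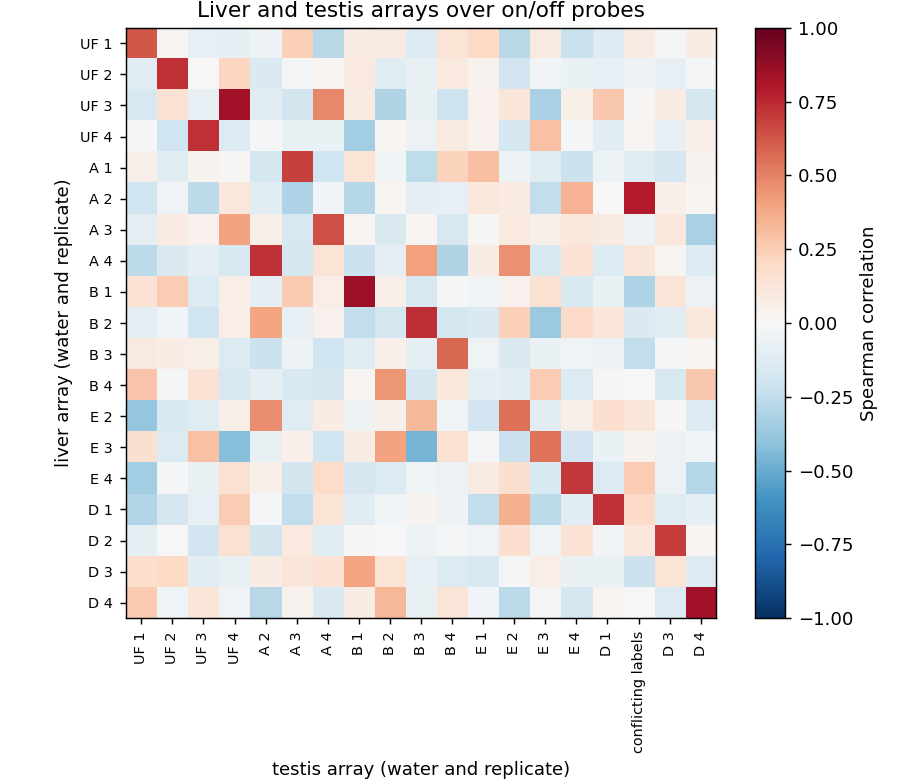
Spearman correlation over 58 on/off probes between each liver array (y axis) and each testis array (x axis), labelled by water and replicate. The array with conflicting labels has its highest value, 0.79, with liver site A replicate 2.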

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

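The test with the neighbours of dark spots and the test of the other site E testes were chosen after those results were seen; the spike-in and slope tests were fixed first. In 11 of 121 groups of 4 arrays the highest or lowest array stood far from the others, where chance, at about 1 in 20 groups, gives 6.05.

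The lowest mean correlation with the other testis arrays in its group belonged to site B replicate 3 (0.927 against 0.950 to 0.953, gap ratio 0.888). On this array 90.4% of the 146 probes lowered at least 8-fold against the testis median lay in a dark central patch, as did 92.7% of the 289 on site E replicate 3. Of these lowered probes, 88.4% and 92.0% had another within 2 rows and columns, against at most 32.2% and 45.7% in 100 random draws, which argues against lower transcript levels in these fish. Spike-in control spots inside the patch were dimmer than copies of the same controls outside it, with a median log2 difference of -2.16 on site B replicate 3 and -2.38 on site E replicate 3, and of 0.10 at the same places of site E replicate 1. A hybridization defect within the array is therefore a candidate explanation, and what produced it stays open.

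Over 262 probes at least 64-fold higher in liver than in testis, site E replicate 3 had a median of -0.58, with the other site E testes at -5.11 to -4.85 (gap ratio 0.943). The other site E testes had a median of -4.89, within the UF control range of -4.92 to -3.48, which argues against an effect of site E water on this group as a whole. Liver RNA in the testis sample would add a constant share of each liver level: the slope of log2 excess on log2 liver level was 1.09 (95% interval 1.03 to 1.16), and the median excess was 3.30% of the liver level. Only 72.9% of the probes were raised at least 4-fold, under the 80% set in advance, with 77.5% outside the dark patch and 59.3% (slope 1.11) without the 100 in which the pattern was first seen, so liver RNA may be present but was not established. At an excess of 3.30% of the liver level, probes near the 64-fold bound would rise less than 4-fold even with liver RNA present. The share under 80% can therefore not decide the question. A difference in this fish itself was not tested.

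Non-uniform spots set apart liver UF control replicate 4 (92 against 0 to 7, ratio 0.924), liver site A replicate 3 (1143 against 0 to 5, ratio 0.996) and liver site D replicate 4 (35 against 0 to 2, ratio 0.943). They also set apart testis site E replicate 2 (344 against 5 to 51, ratio 0.864). Testis site D replicate 1 had the lowest mean correlation of its group (0.953, with the others at 0.955, ratio 0.852). Among named probes, UF_Ppr_AF_112711 was highest in liver site A replicate 3 (0.16 against -1.01 to -0.86, ratio 0.869), and UF_Ppr_AF_115273 in liver site D replicate 1 (0.61 against -1.25 to -1.02, ratio 0.879). UF_Ppr_AF_103904 was lowest in testis UF control replicate 3 (3.61 against 4.69 to 4.72, ratio 0.970), and UF_Ppr_AF_109256 in testis site B replicate 3 (-4.70 against -4.09 to -3.97, ratio 0.835).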

How the results depend on the processing

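The fits without the 3 arrays that stand apart, with the dark patch set to missing and, for the tissue difference, with fish as a random block or the array with conflicting labels moved or left out, were chosen after seeing the data. The 3 arrays are liver site A replicate 3, testis site B replicate 3 and testis site E replicate 3. In limma no comparison of waters had a call under normexp and quantile, quantile, median scaling, the authors' values, no filter, the stricter filter, outlier spots kept, the dark patch set to missing (testis), the replicate block (0 in each of 14), or the array with conflicting labels left out or placed in site A; unadjusted counts under the authors' values ran from 328 to 997. Liver site A against site D had 1 call with the slide as a block (UF_Ppr_AF_104571), 1 without the 3 arrays (UF_Ppr_AF_107647) and 2 with both. In site D livers UF_Ppr_AF_104571 was well above background only on replicate 4. Testis site A against UF control had 1 with only the 2 groups (UF_Ppr_AF_117050) and 3 with array weights. Testis site B against site D had 3 with only the 2 groups (UF_Ppr_AF_101077, UF_Ppr_AF_114560 and UF_Ppr_AF_104603) and 1 with the slide as a block (UF_Ppr_AF_104603). In site B testes these 3 probes were well above background on at most 1 array. Testis site E against site D had 1 with trend and robust moderation (UF_Ppr_AF_105723) and 1 without the 3 arrays (UF_Ppr_AM_119974). UF_Ppr_AM_119974 was well above background on no site D testis, and not on site E replicate 3, which that fit left out. The tissue difference for site A had 1 call (UF_Ppr_AF_105208) under quantile, the authors' values and fish as a random block. Leaving out each array in turn gave 0 to 1 calls in liver site A against UF control and against site D (without site A replicate 2 UF_Ppr_AF_117050, without replicate 3 UF_Ppr_AF_107647), and in 3 testis comparisons: site B against UF control (without UF control replicate 4, UF_Ppr_AF_112593), site A against site D (without site A replicate 3, UF_Ppr_AF_117725) and site E against site D (without site E replicate 3, UF_Ppr_AM_119974). These probes outside the naming rule were chosen after their values were seen, and the cause was not tested. Whether more probes were higher or lower at an unadjusted p under 0.05 depended on the scaling and on single arrays: of the 14 comparisons, only testis site E against UF control kept its majority under median scaling, quantile, normexp and quantile, and the authors' values. Liver site A against UF control had 276 higher and 461 lower, 506 and 298 under median scaling, and 261 and 236 without site A replicate 3; testis site B against site D had 273 and 430, and 442 and 208. The 50 named differences kept their direction in all 1141 alternatives, and passed in 4. They were chosen by p on the same arrays that the alternatives refit. A change of direction was therefore unlikely, and the kept directions are no independent evidence. Same-numbered arrays did not pair: 8 of 48 deviations correlated above 0.1. With the control arrays split, correlations of responses were, in liver, -0.0230 for site A and site B, 0.113 for site A and site E, 0.00259 for site A and reference site D, 0.0280 for site B and site E, 0.0255 for site B and reference site D, 0.0889 for site E and reference site D; in testis, 0.00566 for site A and site B, -0.0826 for site A and site E, -0.0988 for site A and reference site D, 0.0623 for site B and site E, -0.107 for site B and reference site D, 0.0204 for site E and reference site D; splitting takes away the shared controls. The scan day as a block (1 day per tissue), the mean over a gene's probes and the gene lists were not run. Signal over background limits liver slide 2.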

Other observations

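The tissue contrast, the probe described after it and the split counts were chosen after results were seen; the tests of the conflicting label were fixed first. Liver and testis of the UF control fish differed over much of the array, in a contrast confounded with slide and scan day. With the slide as a random block, limma called 4201 probes higher in liver and 3660 higher in testis of 13628 (53.4% higher in liver). With median scaling 62.6% of the calls were higher in liver, and the median difference moved from 0.12 to 0.47. At a log2 difference over 5, 387 probes were higher in liver and 710 in testis. UF_Ppr_AF_108969 (contig FJU.94.C1___1_nrnt) averaged 7.23 ± 0.42 in liver and -5.04 ± 2.74 in testis (SD, n = 4). UF_Ppr_AF_100247 (contig FJU.779.C1___1_nrnt) averaged -3.32 ± 0.81 in liver and 5.44 ± 0.58 in testis (SD, n = 4).

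Probe UF_Ppr_AF_117050 (contig FJU.1857.C1___1rc_nrnt), chosen after its values were seen, was on in most fish and off in others, and was one of the 58 probes used to match the tissues. It read -8.71, -7.58 and -8.25 in liver site A replicates 1, 3 and 4, -2.18 in replicate 2, and -3.02 to -2.85 in UF control livers. In testis it read -6.90, -7.81 and -8.83 in site A replicates 2, 3 and 4, and -1.05 in the array with conflicting labels, whose matching liver is site A replicate 2. It was not well above background in liver site B replicate 2 (-5.94) or testis site B replicate 3 (-8.08), which match each other. The same held for liver site B replicate 3 (-4.43). Both livers lay on dim liver slide 2, so whether the probe was off in them is uncertain. The testis value equals that of UF_Ppr_AF_101077, also at background on that array, which carried a dark patch. The match of liver site B replicate 3, testis site B replicate 4 (-3.12), was among the higher arrays. Testis site E replicate 1 (-7.54) had no matching liver.

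The label of the conflicting testis array was weighed on 147 probes with smaller on/off gaps, not used to find the match and with the tests fixed first. Its highest correlation with any site D liver was 0.0921, below the 0.617 with a site A liver, replicate 2. If that liver is labelled rightly, this argues against a wrong title with site D as the true water. Whether that liver carries a wrong label was not tested, and the match cannot tell. The second best of all livers was 0.102. A wrong source name with site A as the true water is therefore a candidate explanation, and its placement was not altered for the comparisons. No biological explanation was tested.

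The number of probes at an unadjusted p under 0.05 was compared with that of all 35 splits of the same arrays into groups of the same sizes, the real one included. This measure was chosen after the results were seen, because the adjusted counts were 0. Chance could not be excluded for any of the 14 comparisons. In liver these were site A against UF control (737 probes, 17 splits, highest other 1386), site B against UF control (540 probes, 6 splits, highest other 633), site E against UF control (389 probes, 10 splits, highest other 922), site D against UF control (440 probes, 11 splits, highest other 1226), site A against site D (909 probes, 8 splits, highest other 1514), site B against site D (518 probes, 6 splits, highest other 773) and site E against site D (309 probes, 19 splits, highest other 594). In testis they were site A against UF control (551 probes, 11 splits, highest other 1152), site B against UF control (474 probes, 22 splits, highest other 1479), site E against UF control (784 probes, 11 splits, highest other 1833), site D against UF control (323 probes, 32 splits, highest other 765), site A against site D (600 probes, 8 splits, highest other 721), site B against site D (703 probes, 12 splits, highest other 986) and site E against site D (404 probes, 27 splits, highest other 1867). Among other splits, 11 probes passed in limma in the testis split of site E and site D arrays with 1867 probes. That points to a structure of these arrays, and the split was among the most uneven in slides. So were the highest other splits for testis site E against UF control (1833), liver site D against UF control (1226) and liver site E against site D (594). With the slide as a block, the real splits gave 346 for testis site E against site D and 681, 457 and 234 for these. In the other comparisons the highest other split was not among the most uneven. Unevenness did not always go with a high count: for liver site D against UF control, the other splits as uneven as the highest gave 212 to 576. For liver the most uneven splits reached 1154 for site A, 614 for site B and 337 for site E against UF control, and 1277 and 575 for sites A and B against site D. The medians over the other splits were 646.5, 362, 301, 714 and 337. For testis they reached 415 for site A, 915 for site B and 696 for site D against UF control, and 374 and 760 for sites A and B against site D. The medians there were 469, 580.5, 449, 422 and 564.5.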
